A study of Mus musculus with 8 samples.

How the data were processed

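Gene expression was measured on a whole-transcript Affymetrix gene array in hepatic stellate cells, the vitamin A storing pericytes of the liver sinusoid, from male Balb/c mice. Cells of normal mice (quiescent group, 4 arrays) were compared with cells of mice that had received 4 injections of carbon tetrachloride (CCl4), a hepatotoxin that induces liver fibrosis, at 0.5 µl per g body weight and 2 per week, and had then rested for 45 days (reverted group, 4 arrays). Per the labels' protocols, stellate cells were enriched by density centrifugation, sorted on the autofluorescence of their retinoids and lysed right after the sort. RNA was column-purified, and 150 ng was amplified and biotin-labelled with the Ambion WT Expression and GeneChip WT Terminal Labeling kits. The labels give the age of both groups as 18 weeks in a general statement and that of the reverted group as 16 weeks in a group statement, and this contradiction was not settled. No label says whether each array holds cells of a single mouse or of a pool, so the p-values measure only the spread between these samples, which may be technical. No hybridisation batch or scan date was given in the sources used here.

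The deposited values are on a log2 scale and were made with RMA, which corrects background, normalizes across arrays and summarises the probes of each probe set, per the submitters' processing notes. The RMA version and settings and the genome build were not given in the sources used here. The 8 columns of the table were matched to the samples by name, and 0 columns were without a sample. The table holds 35556 probe sets with 0 missing values, and the log2 values of each array ran from a minimum between 4.49 and 4.57 to a maximum between 14.7 and 14.8. Background levels were not used here, so that changes of dim genes on this compressed scale may be understated, and the number of arrays limits the precision.

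Gene symbols came from the platform's annotation table, which lists 23410 of the probe sets and leaves 12146 unnamed here. Of the listed probe sets, 21789 carry 1 gene symbol and 1621 carry several, and no gene was named from the latter. The Entrez identifiers of 21698 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which was used for names only, and 0 symbols needed an update. For the 999 genes with several probe sets, the probe set with the highest mean over the 8 arrays was used, which left 19938 genes. No filter on dim genes was applied.

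Reverted and quiescent arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, without covariates and with Benjamini-Hochberg adjustment over the 19938 genes. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Genes with an adjusted p under 0.05 were called changed, and a count with a minimum of 1.5-fold was added. Fold changes are reverted over quiescent, and errors are the SE from the limma fit. The 38 gene lists (27 of pathways and 11 of cell type markers, with 1045 of 1154 entries measured) were tested with camera in limma at a preset inter-gene correlation of 0.01, against all other genes tested, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Each list also has the count of members past an adjusted p of 0.05 over all genes and adjusted over the list alone.

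The 38 lists, the tests of genes and lists, the rule for naming genes and the alternatives given below, except those said to be added, were fixed before the data were examined. The text names the 12 genes with the largest rise and the 12 with the largest fall among those called changed whose 4 reverted arrays all lay on one side of all 4 quiescent arrays, leaving out predicted and unnamed genes. It also names a set of 20 core stellate genes whatever their test, and up to 4 members of each list with the smallest p. The core gene Spp1 had no probe set with a single gene symbol in the annotation and is not analysed here, and another core gene is not reported here.

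The limma steps were tested on simulated data for this comparison, with 200 of 19938 genes changed. At a log2 change of 0.58, 91% of the changed genes were recovered and 7.14% of the calls were false. The recovered shares were 99% at a log2 change of 1 and 100% at 2. The simulation drew normal noise independently for each gene, with its SD within the groups, and picked the changed genes at random. Genes of the real arrays vary together, so these shares may not hold for them.

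The alternatives were quantile normalization of the 8 columns, centring of each array on its median, leaving out the lowest 25% or the lower 50% of genes by mean level, the mean of all probe sets per gene, all probe sets with no choice per gene, an intensity trend with robust variance, array weights, Welch's test per gene, the replicate number as a block, and leaving out each array in turn. The mean of the hepatocyte markers and the mean of the immediate early genes as a covariate were added after the data had been seen. The 35 ways of splitting the 8 arrays into 4 and 4 were also run.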

Results

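Gene expression was profiled in 8 preparations of sorted mouse hepatic stellate cells, with 4 arrays from normal mice (quiescent) and 4 from mice rested for 45 days after 4 CCl4 injections (reverted). The comparison asks how far stellate cells that had passed through liver injury and its resolution differ from cells that had not been exposed. Median log2 values of the 8 arrays lay between 7.66 and 7.74. In a principal component analysis, the component with the largest share of variance held 35.3% and placed the 4 reverted arrays between 6.07 and 11.5. Quiescent array 4 lay at -0.21 and the other quiescent arrays between -14.0 and -8.79. Across genes, quiescent array 4 correlated at 0.9968 and 0.9964 with quiescent arrays 1 and 2. Its correlation with quiescent array 3 and with reverted arrays 2 and 3 was 0.9972, and its array weight was the lowest (0.584). The component with the next largest share held 17.9% and placed quiescent array 3 at -11.5 and reverted array 1 at -12.3, with the other 6 arrays between 0.25 and 6.78. All values that follow rest on n = 4 arrays per group, and log2 changes are reverted minus quiescent.

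In limma, the sorted cells of the reverted group carried more Gpx3, Dpt, Wt1 and Lox mRNA and less Sectm1a, Tafa1 and Gfap mRNA than quiescent cells. With each array left out in turn, the calls of Wt1, Lox, Sectm1a and Tafa1 held, while those of Gpx3, Dpt and Gfap did not. With the hepatocyte marker mean as a covariate Gpx3, Dpt, Wt1 and Gfap lost their calls. Dpt and Wt1 are also markers of portal fibroblasts or mesothelium. The stellate markers Lrat, Des, Pdgfrb and Hgf did not pass the test, with log2 changes between -0.03 and 0.00. Their probe sets lie at level percentiles 98 to 99.9, near the top of the scale, where a difference can be compressed. Of 19938 genes, 142 changed in limma with Benjamini-Hochberg adjustment, of which 105 rose and 37 fell. The called rises had a median log2 change of 0.56 and the called falls of -0.48. At least 1.5-fold changes were found in 59 of these genes, with 49 rises and 10 falls. In each of the 142 genes, all 4 reverted arrays lay on one side of all 4 quiescent arrays, a separation that selection by a small p makes likely. Among all genes, 8.73% showed such a separation, against 2.86% by chance.

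The largest rise was that of Gpx3, which encodes the secreted glutathione peroxidase, from a log2 level of 8.79 ± 0.60 (SD, n = 4) in quiescent to 10.76 ± 0.34 (SD, n = 4) in reverted cells, or 3.92-fold (adjusted p = 0.0174). Dpt, encoding the matrix protein dermatopontin, rose 3.23-fold, with a log2 change of 1.69 (SE 0.24, adjusted p = 0.0174). Cyp7b1, an oxysterol 7-alpha-hydroxylase, rose 2.99-fold, with a log2 change of 1.58 (SE 0.18, adjusted p = 0.00808). Wt1, a transcription factor of mesothelium and of liver mesenchyme in development, rose 2.62-fold, from 8.19 ± 0.21 to 9.57 ± 0.33 (SD, adjusted p = 0.00801). Clic5, an intracellular chloride channel protein, and Svep1, an extracellular matrix protein, rose by 1.32 (SE 0.13) and 1.30 (SE 0.11) on the log2 scale. The remaining genes among the 12 largest rises were the secreted protein gene Lgi2 (1.27), the aminopeptidase A gene Enpep (1.27), the EGF receptor ligand Ereg (1.27), Tmem108 (1.25), the LIM domain gene Fhl2 (1.20) and the L-type calcium channel subunit Cacna1c (1.17), with adjusted p between 0.00171 and 0.0276. Without reverted array 3 the adjusted p of Gpx3 was 0.0514 and that of Dpt 0.0514, and without reverted array 4 that of Dpt was 0.0703. Fhl2 lost its call without quiescent array 2 (0.062), reverted array 3 (0.0886) or reverted array 4 (0.0703). Ereg lost its call without quiescent array 1 (0.0818) or 2 (0.0726) or without reverted array 1 (0.0621), 3 (0.104) or 4 (0.106). With the hepatocyte marker mean as a covariate Gpx3 (0.0983), Dpt (0.1), Wt1 (0.0612), Ereg (0.0835) and Fhl2 (0.0835) lost their calls, and with the immediate early gene mean Gpx3 (0.106), Dpt (0.107) and Cyp7b1 (0.0512) did. In the latter fit the log2 changes of Gpx3, Dpt and Cyp7b1 were 1.91, 1.63 and 1.45, against 1.97, 1.69 and 1.58 without a covariate.

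Among the falls, Sectm1a was lower by the widest margin, with a log2 change of -1.27 (SE 0.11, adjusted p = 0.00171) from 8.86 to 7.60. Tafa1, a secreted chemokine-like protein, had a log2 change of -1.02 (SE 0.10, adjusted p = 0.00326). The other falls included Sorcs3 (-0.99), the kainate receptor partner Neto1 (-0.87), the transcription factor Gata5 (-0.83), the protocadherin Pcdh15 (-0.81), the heparan sulfate sulfotransferase Hs6st3 (-0.70), the netrin receptor Dcc (-0.65), the transporter Abca8a (-0.61), the Notch target Hey1 (-0.59), the thrombomodulin gene Thbd (-0.57) and the clusterin gene Clu (-0.56), with adjusted p between 0.00801 and 0.046. Dcc (0.0672) and Abca8a (0.0702) lost their calls without reverted array 4 alone, and Gata5 did so without reverted array 2 (0.0683), 3 (0.0776) or 4 (0.107). Hey1 lost its call without quiescent array 1 (0.0875) or reverted array 1 (0.055), 2 (0.0772) or 4 (0.0981). Sorcs3 lost its call without quiescent array 1 (0.0935) or 3 (0.075), or reverted array 2 (0.0769), 3 (0.105) or 4 (0.0902). Thbd lost its call without each array except quiescent array 2, with a highest adjusted p of 0.138, and Clu without each array except reverted array 3, with a highest adjusted p of 0.113. Of these 12 falls only Sectm1a and Tafa1 kept their calls with the hepatocyte covariate, where the other 10 ran from 0.052 (Pcdh15) to 0.134 (Clu). The immediate early gene covariate ended 8 of the 12 calls, all but those of Sectm1a, Tafa1, Neto1 and Abca8a, with adjusted p from 0.0512 (Dcc) to 0.157 (Sorcs3). In that fit the log2 changes of these 8 genes lay between -0.88 (Sorcs3, against -0.99 without it) and -0.51 (Hey1, against -0.59).

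**Figure D1:**
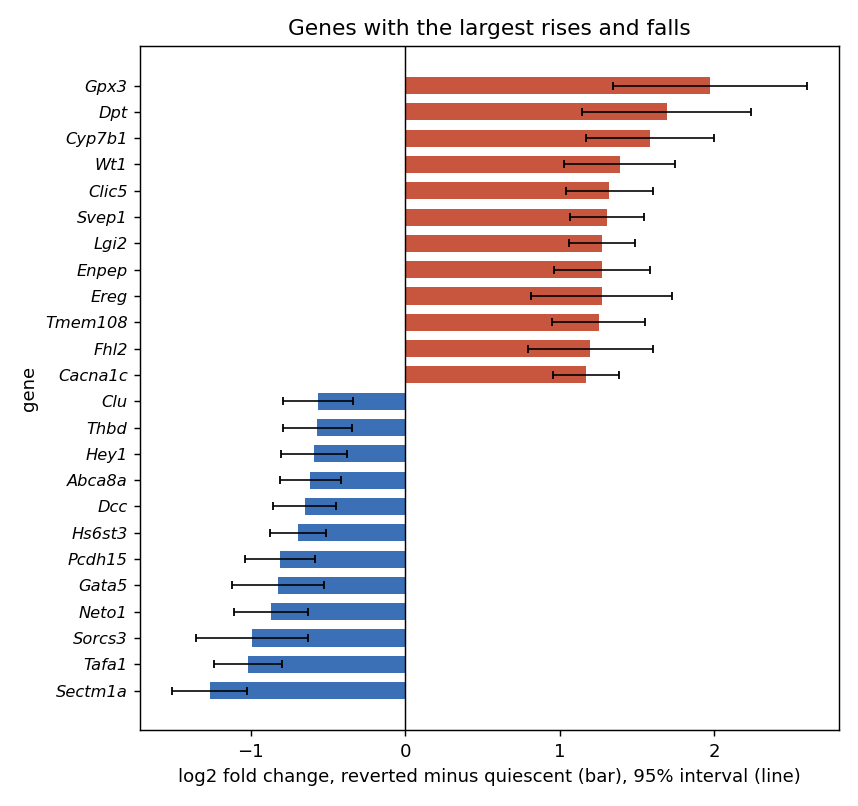
Log2 change of reverted against quiescent stellate cells (bars) with its 95% interval from limma (lines) for the 12 largest rises and the 12 largest falls among genes past the limma test with non-overlapping arrays. Changes run from 1.97 for Gpx3 to -1.27 for Sectm1a.

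The stellate quiescence and retinoid storage list had 34 measured members, of which Gfap fell and 33 did not pass the test. Gfap, a glial intermediate filament protein that marks quiescent stellate cells, went from 9.44 ± 0.12 to 8.95 ± 0.10 (SD), a log2 change of -0.49 (SE 0.07, adjusted p = 0.0182). Without reverted array 4 its adjusted p was 0.0703, and with the hepatocyte or immediate early gene covariate 0.0991 or 0.106. The log2 change of Gfap in these fits was -0.46, -0.39 and -0.50. Lrat, which esterifies retinol for storage, had a mean log2 level of 14.05 in quiescent and 14.04 in reverted cells (adjusted p = 0.997), and the intermediate filament gene Des stood at 12.81 and 12.79 (adjusted p = 0.877). The adipogenic regulator Pparg (-0.03, adjusted p = 0.839), the lipid droplet gene Plin2 (-0.09, adjusted p = 0.387), the TGF-beta pseudoreceptor Bambi (-0.15, adjusted p = 0.431), the neurotrophin receptor Ngfr (-0.20, adjusted p = 0.176), the growth factor gene Hgf (-0.03, adjusted p = 0.754) and the adiponectin receptor Adipor1 (0.08, adjusted p = 0.4) did not pass the test either. Pparg lay at level percentile 30, where a change may be understated. In this list 9 members had a higher and 25 a lower mean in reverted cells, with a median log2 change of -0.03. Pde3b (0.28, adjusted p = 0.102) and Angptl6 (-0.18, adjusted p = 0.143) had the next smallest p values. Of its members, 1 rose and 1 fell when adjusted over the list alone. The list was not shifted in camera (adjusted p = 0.109). It passed without reverted array 2 (0.0384), and also without the lower 50% of genes by level (0.00443) or with an intensity trend and robust variance (0.0475).

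The stellate activation and contractile list was shifted up in camera with the preset correlation (adjusted p = 0.000679), with an adjusted p = 0.188 with an estimated correlation. Of 35 measured members, 3 rose, 0 fell and 32 did not pass the test, and the mean log2 change was 0.21 with a median of 0.09. The risers were Dpt, Lox, which encodes a collagen cross-linking oxidase, and Tnc, which encodes tenascin C. Lox went from 6.48 ± 0.19 to 7.53 ± 0.19 (SD), or 2.07-fold (adjusted p = 0.00519), and Tnc had a log2 change of 0.80 (adjusted p = 0.0238). Of its members, 6 rose and 0 fell when adjusted over the list alone. The myofibroblast actin gene Acta2 was at 8.20 ± 0.29 in quiescent and 8.70 ± 0.26 in reverted cells (SD, adjusted p = 0.188), and the metalloproteinase inhibitor Timp1 had a log2 change of 0.62 (SE 0.17, adjusted p = 0.14), so neither passed. For Timp1 each reverted array nevertheless lay above each quiescent array, while the arrays of Acta2 overlapped. The fibronectin gene Fn1 (0.25, adjusted p = 0.0632) also lay short of the limit, and Pdgfrb (adjusted p = 0.988) and Tgfb1 (adjusted p = 0.902) were at 0.00 and -0.02. Markers of hepatocytes were also higher in the reverted group, with a mean log2 shift of 0.38, although their ranges per array overlapped. Tnc lost its call without any array except quiescent 4 or reverted 1, and its highest adjusted p was 0.0769, without reverted array 4. The adjusted p of Dpt was 0.0514 without reverted array 3 and 0.0703 without reverted array 4. The hepatocyte and immediate early gene covariates ended the calls of Tnc (0.0991 and 0.136) and Dpt (0.1 and 0.107) but not that of Lox. In these fits the log2 change was 0.83 and 0.76 for Tnc and 1.61 and 1.63 for Dpt.

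Fibrillar collagen genes did not move as a set. Of 25 measured members of the fibrillar and associated collagen list, 0 rose and 0 fell over all genes in limma, 12 had a higher and 13 a lower mean, and the list's camera adjusted p was 0.365. Its members included 5 rises and 1 fall adjusted over the list alone. The core genes Col1a1 (0.32, SE 0.12, adjusted p = 0.239), Col1a2 (0.10, adjusted p = 0.447) and Col3a1 (-0.03, adjusted p = 0.806) did not pass, nor did the prolyl hydroxylase P3h2 (0.45, adjusted p = 0.0611) or Col8a1 (0.55, adjusted p = 0.0985). The list's median was -0.02, while its mean was 0.05 and its camera direction up, and the direction was down (adjusted p = 0.492) without the lower 50% of genes by level.

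**Figure D2:**
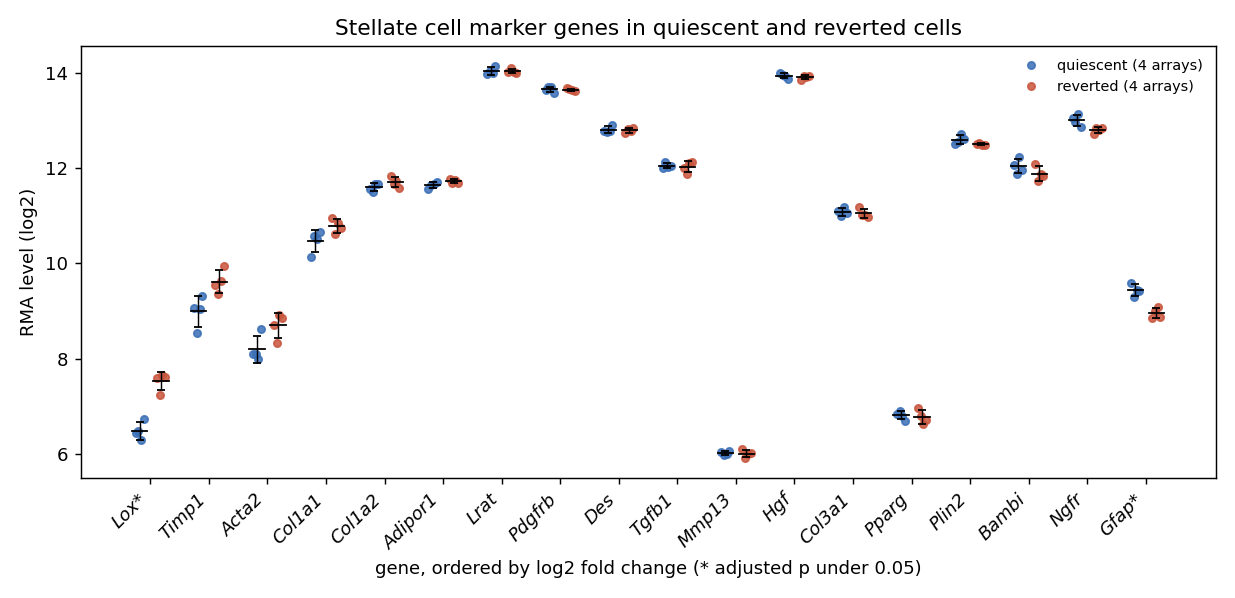
Log2 level of each core stellate gene in each of the 4 quiescent and 4 reverted arrays, with the group mean and SD. Lox (7.53 against 6.48) and Gfap (8.95 against 9.44) are the genes among these that passed the limma test.

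Genes of the basement membrane were shifted up in camera with the preset correlation (adjusted p = 0.000326), with an adjusted p = 0.188 with an estimated correlation. Of 18 measured members 2 rose, the laminin chain genes Lama4 (0.34, adjusted p = 0.0174) and Lama2 (0.52, adjusted p = 0.0277), 0 fell and 16 did not pass. The type IV collagen genes Col4a2 (0.30, adjusted p = 0.0792) and Col4a1 (0.23, adjusted p = 0.0908) came next. A total of 6 rose and 0 fell adjusted over the list alone. Lama4 lost its call without reverted array 2 (0.0518) or 4 (0.0703), and Lama2 without quiescent array 1 (0.0676) or reverted array 1 (0.0632), 2 (0.0667), 3 (0.0909) or 4 (0.106). With the hepatocyte and immediate early gene covariates neither passed, at 0.0991 and 0.0578 for Lama4 and 0.0564 and 0.155 for Lama2. Among 31 matrix proteases and inhibitors 3 rose and 0 fell, namely the disintegrin metalloproteinases Adam12 (0.44, adjusted p = 0.00964) and Adamts12 (0.39, adjusted p = 0.011) and the matrix metalloproteinase Mmp23 (1.02, adjusted p = 0.0188). The counts were 6 up and 1 down when adjusted over the list alone, and camera gave an adjusted p = 0.0318, with an adjusted p = 0.455 with an estimated correlation. The list lost its call without quiescent array 3 (0.0551) or reverted array 1 (0.142), and Mmp23 lost its own without reverted array 3 (0.0649) or 4 (0.0703). The list's adjusted p was 0.0528 with the hepatocyte marker mean and 0.119 with the immediate early gene mean as a covariate, and 0.0714 without the lower 50% of genes by level. The same covariates ended the call of Mmp23 (0.109 and 0.102), while Adam12 lost its call with the hepatocyte (0.0593) and Adamts12 with the immediate early gene covariate (0.0729). The protease genes Ctsk (0.38, adjusted p = 0.13) and Mmp13 (-0.02, adjusted p = 0.847), the collagenase that degrades fibrillar collagen in rodents, did not pass. Mmp13 lay at level percentile 14.6, where a change may be understated. The group mean of hepatocyte markers was shifted by 0.38, with overlapping ranges per array.

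In the TGF-beta and BMP list, 2 of 37 measured members rose and 0 fell. They were Bmp6, a BMP ligand that controls hepcidin expression (0.92, adjusted p = 0.00171), and Ltbp1, which binds latent TGF-beta (0.60, adjusted p = 0.016, and 0.055 without quiescent array 1). Ltbp1 did not pass with the hepatocyte (0.0959) or the immediate early gene covariate (0.0578). Its members included 5 rises and 3 falls adjusted over the list alone. The BMP target Id1 (-0.61, adjusted p = 0.105) and the ligand Tgfb2 (0.70, adjusted p = 0.123) did not pass. The list did not shift (camera adjusted p = 0.777). Its median was -0.01 against a mean of 0.04, and its direction was up as deposited but down after quantile normalization, without reverted array 3 (0.803) and with the immediate early gene covariate (0.985). Of 29 growth factor and vasoactive receptors 0 rose and 0 fell in limma, with 1 rise and 2 falls adjusted over the list alone. Fgfr1 (-0.44, adjusted p = 0.0571) and the endothelin receptor Ednrb (0.15) were among those with the smallest p, and the list's adjusted p was 0.74 in the down direction, with a median of 0.01 and a mean of -0.01. The direction was up without quiescent array 2 (0.962) and with the immediate early gene mean as a covariate (0.985). Of 40 hedgehog, Wnt and Notch genes, Hey1 fell and 0 rose. A total of 3 rose and 6 fell adjusted over the list alone, and the camera adjusted p was 0.132. The list passed in the down direction without the lowest 25% (0.0372) or the lower 50% (0.0365) of genes by level. Notch3 (0.71, adjusted p = 0.118) and the secreted Wnt antagonist Dkk3 (0.72, adjusted p = 0.142) did not pass. Hey1 lost its call without quiescent array 1 (0.0875) or reverted array 1 (0.055), 2 (0.0772) or 4 (0.0981), and with the hepatocyte (0.104) or immediate early gene covariate (0.155).

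Among 44 chemokines and cytokines 3 rose and 0 fell. Cxcl14 (1.08, adjusted p = 0.00282), the lymphoid chemokine Ccl19 (0.57, adjusted p = 0.00423) and Ccl6 (0.28, adjusted p = 0.023) were higher in all 4 reverted arrays than in all 4 quiescent arrays. Ccl6 lost its call without quiescent array 1 (0.0718) or 2 (0.0575) or reverted array 1 (0.0515), 3 (0.0924) or 4 (0.0875), and with the hepatocyte (0.111) or immediate early gene covariate (0.119). The counts were 4 up and 1 down when adjusted over the list alone. The list as a set had an adjusted p of 0.132 as deposited, of 0.00746 after quantile normalization and of 0.04 without reverted array 2. Of 21 NF-kB targets, Ptgs2, which encodes the inducible cyclooxygenase, rose (0.47, adjusted p = 0.0322), 0 fell, and 18 had a higher mean. Its members included 2 rises and 0 falls adjusted over the list alone. Camera gave the NF-kB targets an adjusted p = 0.000679, with an adjusted p = 0.688 with an estimated correlation. With the immediate early gene mean as a covariate it was 0.482, and without the lower 50% of genes by level 0.221. Against the quiescent mean, the NF-kB list stood at 0.33 and 0.32 in reverted arrays 3 and 4. In reverted arrays 1 and 2 it stood at 0.05, inside the quiescent range of -0.10 to 0.14. Ptgs2 lost its call without quiescent array 1 (0.102), 2 (0.0717) or 3 (0.0848) or reverted array 3 (0.121) or 4 (0.0672), and with the hepatocyte (0.115) or immediate early gene covariate (0.155). Tnfaip2 (0.83, adjusted p = 0.0562) did not pass. The 36 immediate early genes, which respond within minutes to stimuli and to cell handling, had 26 higher means, 0 rises and 0 falls in limma, and 2 rises adjusted over the list alone. Their shift had an adjusted p = 0.00284 in camera, and an adjusted p = 0.688 with an estimated correlation. Without quiescent array 3 it was 0.229, and without the lower 50% of genes by level 0.186. Myc (0.70, adjusted p = 0.082), Gadd45g (0.51, adjusted p = 0.054) and Klf6 (0.30, adjusted p = 0.141) had the smallest p values. The group mean of hepatocyte markers was higher by 0.38, with overlapping ranges per array.

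Of 26 innate receptors Il6ra, the interleukin 6 receptor chain, rose (0.51, adjusted p = 0.0162), 0 fell, and the list had an adjusted p of 0.944, with 1 rise adjusted over the list alone. Its direction was down in camera but up in fry, without quiescent array 3 (0.866) or reverted array 1 (0.593), with array weights (0.786) and with the hepatocyte covariate (0.708). Il6ra lost its call without quiescent array 1 (0.0572) or reverted array 3 (0.0653) or 4 (0.0572), and with the hepatocyte (0.0755) or immediate early gene covariate (0.102). The 34 interferon-stimulated genes had 10 higher and 24 lower means with 0 rises and 0 falls, also adjusted over the list alone, and an adjusted p of 0.354. Ifit3 (-0.37, adjusted p = 0.269) was among their smallest p values. The direction of the interferon list was down as deposited and up, with an adjusted p of 0.0215, with the hepatocyte marker mean as a covariate. It was also up without quiescent array 1 (0.61) or reverted array 1 (0.733), and it passed in the down direction without quiescent array 2 (0.000167) and without the lower 50% of genes by level (0.0157). Of 25 complement and coagulation genes Thbd fell, 0 rose and 24 did not pass, although 16 had a higher mean. A total of 5 rose and 1 fell adjusted over the list alone, among them the complement genes C7 (0.60, adjusted p over all genes 0.129) and C2 (0.31). The list's camera adjusted p was 0.0211 in the up direction, and the adjusted p = 0.284 with an estimated correlation. Without quiescent array 4 it was 0.0717, and with the hepatocyte marker mean as a covariate 0.0879. Without the lowest 25% of genes by level it was 0.103, and without the lower 50% 0.526. The called member Thbd had a highest adjusted p of 0.138, without reverted array 3, and was at 0.126 or 0.132 with the hepatocyte or immediate early gene covariate. Of 10 MHC class II genes 0 rose and 0 fell, with 1 rise and 1 fall adjusted over the list alone, an adjusted p of 0.288 and Cd74 at 0.28 (adjusted p = 0.127).

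Of 18 cholesterol synthesis genes 17 had a higher mean, 0 rose and 0 fell in limma over all genes, and 4 rose adjusted over the list alone. Sqle (0.17, adjusted p = 0.108), Msmo1 (0.30, adjusted p = 0.133), Idi1 (0.28, adjusted p = 0.133) and Cyp51 (0.22) had the smallest p values. The median was 0.14, the camera adjusted p was 3.58e-05, and the adjusted p = 0.317 with an estimated correlation. Without the lower 50% of genes by level it was 0.0859. Of 41 cytosolic ribosomal protein genes 38 had a higher mean, with a median of 0.07 and Rpl30 at 0.25 (adjusted p = 0.117). Camera gave an adjusted p = 2.05e-06, with an adjusted p = 0.577 with an estimated correlation. Of 56 oxidative phosphorylation genes 49 had a higher mean, with a median of 0.08 and an adjusted p = 1.7e-05, with an adjusted p = 0.688 with an estimated correlation. After quantile normalization the mean log2 change of this list was 0.04 against 0.07 as deposited, with a camera adjusted p of 0.00619, so its size depends on the scaling. The mean of this list in reverted array 2 (10.81) lay inside the quiescent range of 10.76 to 10.88, while the other 3 reverted arrays lay at 10.92 to 10.93. Hepatocyte markers were also higher in the reverted group, by a mean log2 of 0.38, but not in each array. Their mean was 8.90 in quiescent array 2 against 8.66 in reverted array 2. In the ribosomal and oxidative phosphorylation lists 0 members rose and 0 fell, also adjusted over the list alone. Of 43 cell cycle genes 36 had a higher mean, 0 rose and 0 fell, also adjusted over the list alone, and the adjusted p was 0.0112, with an adjusted p = 0.813 with an estimated correlation. In each group the list was highest in the array that stood apart on the component with 17.9% of the variance, at 0.71 above the quiescent mean in reverted array 1 and at 0.15 in quiescent array 3. The cell cycle shift rested on reverted array 1, without which the adjusted p was 0.838, and it was also lost without quiescent array 2 (0.109), with the hepatocyte covariate (0.205), with array weights (0.0679) and without the lowest 25% (0.0608) or lower 50% (0.759) of genes by level. Cdk1 had a log2 change of 0.60 (adjusted p = 0.31).

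The 25 genes of ER stress and the unfolded protein response, with 23 lower means, were shifted down in camera with the preset correlation (adjusted p = 0.00954). The adjusted p was 0.753 with the estimated correlation, which was 0.592, and 0.503 in fry. Creld2 (-0.35), Chac1 (-0.14), Sel1l (-0.09) and Sdf2l1 (-0.37) had the smallest p values, and 0 members rose or fell, also adjusted over the list alone. The shift was lost without quiescent array 1 (0.179) or 4 (0.058), without reverted array 1 (0.223) and with the hepatocyte covariate (0.59). The list mean was lowest in quiescent array 3 (-0.23 against the quiescent mean) and reverted array 1 (-0.24), which also stood apart on the component with 17.9% of the variance. Of 33 adipogenic and lipid droplet genes, Elovl6, a fatty acid elongase, rose (0.96, adjusted p = 0.0116, with 0.0511 without reverted array 3 and 0.0838 or 0.0855 with the hepatocyte or immediate early gene covariate), 0 fell, and 2 rose adjusted over the list alone. The stearoyl-CoA desaturase gene Scd1 (0.46, adjusted p = 0.103) did not pass, and the list had an adjusted p of 0.63 in the up direction, with a mean of 0.04 and a median just below 0. Of 28 retinoid metabolism genes 0 rose and 0 fell, also adjusted over the list alone. Their adjusted p was 0.743, with the direction down as deposited and up after quantile normalization and a mean of 0.02 against a median of -0.01. Of 30 antioxidant and xenobiotic response genes Gpx3 and the cytochrome gene Cyp1b1 (0.85, adjusted p = 0.00171) rose and 0 fell, with 2 rises and 1 fall adjusted over the list alone. That list had an adjusted p of 0.365, with a mean of 0.10 and a median of -0.01, and its member Gpx3 had an adjusted p of 0.0514 without reverted array 3 and of 0.0983 or 0.106 with the covariates. Of 26 glycolysis and hypoxia genes 0 rose and 0 fell, with 3 rises and 1 fall adjusted over the list alone and an adjusted p of 0.116, or 0.0219 without quiescent array 4. The glycolytic genes Hk2 (1.10, adjusted p = 0.0562), Pfkp (0.31, adjusted p = 0.0536) and Tpi1 (0.26, adjusted p = 0.0632) lay just short of the limit.

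Of 19 circadian clock genes 0 rose and 0 fell in limma, 13 had a lower mean, and 1 rose and 1 fell adjusted over the list alone. The repressor gene Nr1d1 (-0.68, adjusted p = 0.0835) and Nfil3 (0.85, adjusted p = 0.0969) had non-overlapping arrays. The list median was -0.23 and its camera adjusted p 0.102 as deposited, 0.0452 after quantile normalization and 0.00591 with the immediate early gene mean as a covariate. It was 0.0166 without quiescent array 1, 0.0349 without quiescent array 3, 0.373 without quiescent array 4 and 0.0418 without the lower 50% of genes by level. Heat shock genes (16 measured, adjusted p = 0.468) and apoptosis genes (25 measured, adjusted p = 0.39) had 0 rises and 0 falls, also adjusted over the list alone. The heat shock list had the direction down as deposited and up without reverted array 1 (0.733) or with the hepatocyte marker mean as a covariate (0.461).

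Among the 11 lists of cell type markers, that of hepatocytes was the one shifted in camera. Of 28 measured hepatocyte markers 25 had a higher mean in reverted cells, with a mean log2 change of 0.38, an adjusted p = 6.72e-06 and an adjusted p = 0.688 with an estimated correlation. Without the lower 50% of genes by level it was 0.0704. The list mean per array ran from 8.14 to 8.90 in quiescent and from 8.66 to 9.09 in reverted cells, so the ranges overlapped. The acute-phase gene Hp rose (0.80, adjusted p = 0.0373) and the transferrin gene Trf fell (-0.27, adjusted p = 0.04), and 26 did not pass. The counts were 7 up and 2 down when adjusted over the list alone. Hpx (0.44, adjusted p = 0.0981) and Apoc1 (-0.56, adjusted p = 0.0948) did not pass. Hp lost its call without each array except quiescent array 2, with a highest adjusted p of 0.13, and Trf without each array except quiescent array 4, with a highest adjusted p of 0.144. Hp (0.11 and 0.169) and Trf (0.0524 and 0.181) also lost their calls with the hepatocyte marker mean, to which both contribute, and the immediate early gene mean as covariates.

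Portal fibroblast and mesothelial markers had 3 rises, Dpt, Wt1 and Gas6 (0.86, adjusted p = 0.0194), and 0 falls among 25 measured members, and 5 rises and 2 falls adjusted over the list alone. Yet 18 of the 25 had a lower mean, the median was -0.07 against a mean of 0.13, and the adjusted p was 0.777, with the direction down as deposited and up after quantile normalization, in fry and without quiescent array 1 (0.929) or reverted array 2 (0.933). Cd34 (0.60, adjusted p = 0.0631) did not pass. Gas6 lost its call without quiescent array 1 (0.0663) or reverted array 3 (0.0634) or 4 (0.0713), and Dpt without reverted array 3 (0.0514) or 4 (0.0703). With the hepatocyte covariate Dpt (0.1), Wt1 (0.0612) and Gas6 (0.109) did not pass, and with the immediate early gene covariate Dpt (0.107) and Gas6 (0.11) did not. Of 16 cholangiocyte markers Bicc1 rose (0.49, adjusted p = 0.00947, and 0.0767 with the hepatocyte covariate), 0 fell, 1 rose adjusted over the list alone, and the list had an adjusted p of 0.961, with the direction down as deposited and up after quantile normalization, in fry and without quiescent array 1, 2 or 3 or reverted array 3 (0.741 to 0.866). Its median was -0.04 against a mean of 0.01.

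In the other 8 lists of cell type markers 0 genes rose or fell over all genes. None of these lists passed camera on the deposited values of all 8 arrays without a covariate, array weights, an intensity trend or a filter on level. The camera adjusted p was 0.156 for 29 sinusoidal endothelial markers, 0.777 for 28 Kupffer cell and macrophage markers, 0.0813 for 20 monocyte and neutrophil markers and 0.0668 for 27 T and NK cell markers. It was 0.0688 for 17 B and plasma cell markers, 0.398 for 19 dendritic cell markers, 0.743 for 22 smooth muscle and pericyte markers and 0.0624 for 9 erythroid markers. Adjusted over the list alone, 1 sinusoidal endothelial and 1 dendritic cell marker rose, and 1 dendritic cell and 1 erythroid marker fell. The Kupffer cell and dendritic cell lists had the direction down as deposited and up after quantile normalization, and the Kupffer cell list was also up without quiescent array 1 (0.973) or 2 (0.707) or reverted array 3 (0.993). It had a median of -0.03 against a mean of 0.02. The smooth muscle list had a median of -0.01 against a mean of 0.08. With the hepatocyte marker mean as a covariate the sinusoidal endothelial list turned from up to down (0.363), while the monocyte and neutrophil (0.0215) and the B and plasma cell lists (0.0287) passed in the down direction. Without quiescent array 4 the monocyte and neutrophil (0.0324), T and NK cell (0.0354), B and plasma cell (0.0131) and erythroid lists (0.0429) also passed in the down direction. The T and NK cell list further passed without reverted array 2 (0.0482), with array weights (0.0337) and with an intensity trend and robust variance (0.0475), and the B and plasma cell list with array weights (0.0337) and without the lowest 25% of genes by level (0.0323). The erythroid list also passed without quiescent array 3 (0.0479) or reverted array 3 (0.0437). After quantile normalization the adjusted p was 0.753 for the monocyte and neutrophil and the T and NK cell lists, 0.64 for B and plasma cells and 0.348 for erythroid markers. These lists are dim. Above the median quiescent level of all genes lay 1 of 20 monocyte and neutrophil, 1 of 27 T and NK cell, 0 of 17 B and plasma cell and 0 of 9 erythroid markers. The sinusoidal endothelial list passed in the up direction without quiescent array 2 (0.00375) or reverted array 2 (0.04). The endothelial lectin gene Clec4g (0.50, adjusted p = 0.063) and the macrophage gene Lyz2 (0.59, adjusted p = 0.129) were among the smallest p values, as were Cd83 (-0.46) and Tfrc (0.56).

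**Figure D3:**
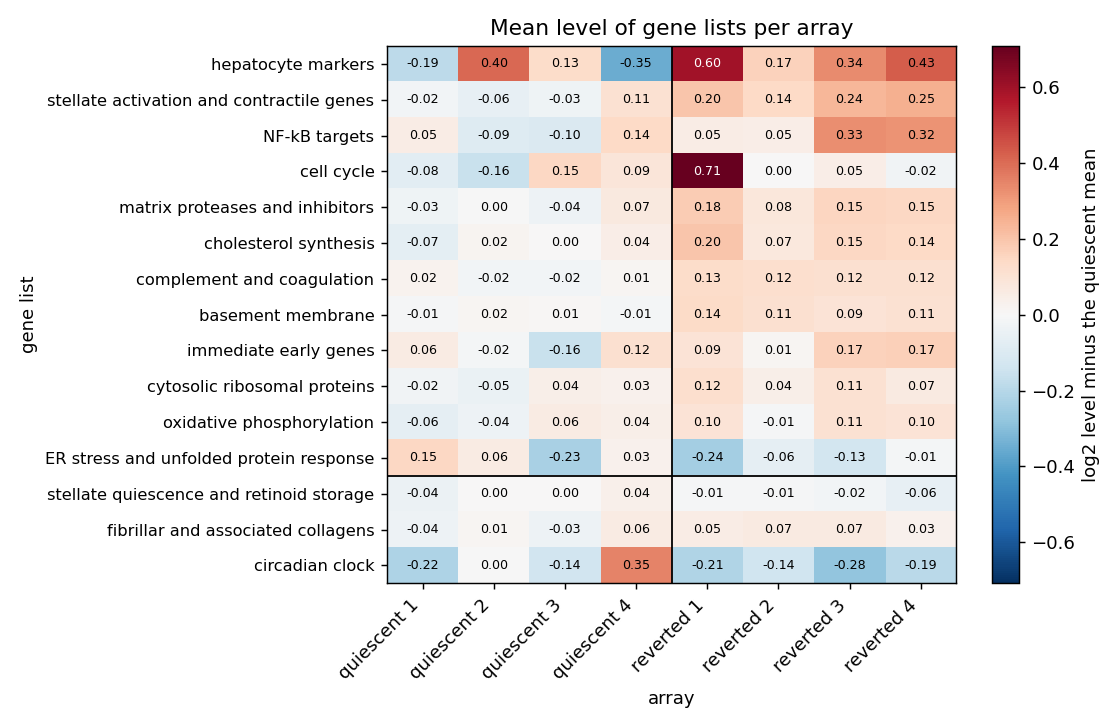
Mean log2 level of each gene list in each of the 8 arrays minus the quiescent group mean, for the 12 lists shifted in camera and for the quiescence, collagen and clock lists. The cell cycle list reaches 0.71 in reverted array 1, and the ER stress list runs from -0.24 to -0.01 in reverted and from -0.23 to 0.15 in quiescent arrays.

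In all, 12 of 38 lists were shifted in camera with the preset correlation, 11 up and 1 down, and 5 of these 12 were still called without the lower 50% of genes by level. With an estimated correlation 0 of 38 lists passed in camera, with 4 at an unadjusted p under 0.05, against 12 with the preset correlation and 3 in fry (basement membrane 0.00676, complement and coagulation 0.0174, activation 0.0181). The estimate itself was 0.0055 for basement membrane, 0.0126 for activation and -0.0215 for complement and coagulation, near or below the preset 0.01. Strongly correlated members are thus not why these lists lost their calls. For the NF-kB (0.517), cell cycle (0.536), ER stress (0.592) and hepatocyte lists (0.613) the estimate lay far above the preset value. The count of 142 changed genes was 73 without quiescent array 1, 247 without quiescent array 4, 59 without reverted array 3 and 54 without reverted array 4, and the count of 59 genes at 1.5-fold was 39 and 33 without reverted arrays 3 and 4. An unmoderated unequal-variance test in R with Benjamini-Hochberg adjustment called 0 genes, with 2369 at an unadjusted p under 0.05 against 3181 in limma, while array weights gave 306 and quantile normalization 219 with 58.4% rises against 73.9%. With the hepatocyte marker mean or the immediate early gene mean as a covariate, both added after the data had been seen, 36 and 39 genes were called, 30 and 25 of 45 named calls ended, and all 142 genes kept their direction. The median size of their log2 change was 0.51 and 0.50 against 0.52 without a covariate. Their median SE was 0.0915 and 0.0817 against 0.0716.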

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

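The tests on other mesenchymal cells and on the time of day, the clock difference with each array left out, and the hepatocyte and immediate early gene covariates as alternatives, were chosen only after the result was seen. Single arrays stood apart from the other 3 of their group in 5 of 164 groups of values checked, where chance marks about 1 in 20 groups, or 8.2 of them. The log2 level of Wt1 was 10.07 in reverted array 1 against 9.36 to 9.46 in the other 3. That of Clic5 was 7.58 in quiescent array 2 against 7.72 to 7.75, and that of Lox was 7.24 in reverted array 2 against 7.60 to 7.66. Calls of these 3 genes held without each array in turn. The mean log2 level of the cell cycle list was 8.67 in reverted array 1 against 7.94 to 8.01, and without this array the list's adjusted p was 0.838. The mean of the oxidative phosphorylation list was 10.81 in reverted array 2 against 10.92 to 10.93 in the other 3.

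Signals were also present in probe sets outside the gene comparison. Of 12146 probe sets that the annotation does not list, 11 changed in limma, 6 of them up. Of 1621 probe sets with several gene symbols 4 changed, all of them up by 0.87 to 1.02. These 4 carry the same set of symbols, so they are not 4 separate signals.

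The activation list was higher in reverted cells by a mean log2 of 0.21 (SE 0.04), with Dpt, Lox and Tnc past the test over all genes. A response to cell isolation was tested with the mean of 35 immediate early genes of each array as a covariate, and the shift stayed at 0.16 (SE 0.04). This argues against that response as the whole cause only as far as the mean of these genes tracks it. That mean was higher by 0.11 in reverted cells, and its ranges per array overlapped (11.86 to 12.15 in quiescent, 12.04 to 12.19 in reverted). A response that these genes measure poorly would not be removed by the covariate. Portal fibroblast, mesothelial and smooth muscle cells cannot be told apart from a change in the stellate cells, because their 40 markers outside the activation list had a mean shift of 0.0602 with 14 higher, and the difference from the activation list, 0.15 (SE 0.08), is under 2 SE. Camera in limma gave these markers a p of 0.765. The sort on retinoid fluorescence would be expected to remove most such cells. A lasting trace of the CCl4 injury, or of the age difference that one label states, may also account for the shift and was not tested apart from the groups.

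Hepatocyte markers were higher in reverted cells by a mean log2 of 0.38, a shift at percentile 100 of 10000 random lists matched on level, which argues against scaling that depends on signal level. A candidate explanation is hepatocyte RNA in the sorted cells. Within the groups the markers rose and fell together, with a mean pairwise correlation of 0.613 across genes against a median of 0.00928 for random lists, as such RNA needs, although genes controlled together in stellate cells would give the same. Alb, with a mean log2 level of 11.9 in quiescent cells, had a change of 0.55 that did not pass, and the falls of Apoc1 (-0.56, adjusted p = 0.0948) and of Trf, whose call ended without 7 of the 8 arrays, do not exclude that source, although the sort would remove most hepatocytes. Of the 28 markers 14 lay above the median quiescent level of all genes and 0 are in another list, and with their mean as a covariate the 142 called genes had a median change of 0.51 against 0.52 and a median SE of 0.0915 against 0.0716, but only 36 genes were called and 30 of 45 named calls ended.

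Output genes of the clock (Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per1, Per2, Per3 and Ciart) had a mean log2 change of -0.49, and the opposite-phase genes Arntl, Clock, Nfil3 and Cry1 of 0.31, although Per1 (0.21) and Cry1 (-0.23) went against their groups. The difference of -0.80 (SE 0.33) had an exact permutation p of 0.0571, 2-sided, where the smallest that 4 against 4 arrays allow is 0.0286. Quiescent array 4 carried much of the shift, since without it the difference was -0.55 (SE 0.25, exact permutation p = 0.114) and the mean change of the whole clock list was -0.09 against -0.21 with all arrays. Without quiescent array 1 the difference was -1.01 (exact permutation p = 0.0286), and with any other array left out it lay between -0.92 and -0.66. A different time of day at isolation and a change of the clock after injury cannot be told apart, since the time of isolation was not given in the sources used here.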

How the results depend on the processing

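The hepatocyte and immediate early gene covariates were chosen only after the result was seen. The count of 142 genes became 219 with quantile normalization (128 up, 91 down), 306 with array weights, 36 with the hepatocyte covariate, 39 with the immediate early gene covariate, 78 of 35556 over all probe sets and 0 in Welch's test (2369 at an unadjusted p under 0.05), and ran from 54 (without reverted array 4) to 247 (without quiescent array 4). With the replicate number as a block it was 63, of which 54 were shared. Deviations of same-numbered arrays correlated at -0.15, -0.03, -0.02 and 0.08 across genes, which gave no sign that the numbers pair the samples. A pairing is not excluded by this, since no label says what the numbers mean. The largest correlation, 0.33, joined quiescent array 3 with reverted array 1, so these 2 arrays share a deviation. The other counts lay between 146 and 184. The count of 59 genes at 1.5-fold became 26 and 28 with the covariates, and 33 to 69 with 1 array left out. Smaller counts without an array go with fewer samples, and larger SEs with the covariates; other causes were not tested. The count of 12 lists became 0 with an estimated correlation and 3 in fry, and lay between 9 and 16 elsewhere. These were not always the same lists: 9 were called without the lower 50% of genes by level, but only 5 of them were among the 12, and 10 of the 12 held without the lowest 25%. The quiescence list passed without the lower 50% of genes (0.00443) and with a trend and robust variance (0.0475), and ran from 0.0384 to 0.285 with 1 array left out. The activation list passed except with an estimated correlation (0.188). The collagen list turned down without the lower 50% of genes (0.492). Other lists that were not called also changed direction without these genes: the TGF-beta, adipogenic, antioxidant and sinusoidal endothelial lists turned down and the Kupffer cell, cholangiocyte and portal fibroblast lists turned up. The immediate early list turned down with its own mean as a covariate (0.736), as this construction forces. Of 45 named calls, 21 held without each array, 13 held under all limma settings that tested them (at most 18), and none reversed in these; none held in Welch's test. Signal over background was not used here, which leaves the limits for dim genes and for genes near the top of the scale unknown.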

Other observations

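The list of ribosome assembly factors, its covariate fits and the genes named in the next paragraph were chosen only after the result was seen. Factors that build ribosomes in the nucleolus, collected by symbol after the called genes had been seen, had mostly higher means in reverted cells. Of 56 measured genes 6 rose and 0 fell, namely Nufip1 (0.73), Nifk (0.36), Utp14a (0.29), Aatf (0.29), Utp4 (0.28) and Utp25 (0.23). Of the remaining 50 genes 48 had a higher mean, with a median log2 change of 0.18 (camera p = 1.99e-17 with the preset correlation, and p = 0.059 with an estimated correlation). After quantile normalization the camera p was 2.7e-12 with the preset correlation. The list was drawn up from these same data, and leaving out the called genes does not make the rest independent of them. These p-values therefore describe the shift and do not test it. Hepatocyte markers were higher in the reverted group by a mean log2 of 0.38, although their ranges per array overlapped. With their mean as a covariate the 50 genes had a mean change of 0.21 against 0.17 without it, and with the immediate early gene mean 0.13. Their direction in camera was up in both fits. In each fit 1 of the 6 calls held. Nufip1 kept its call without each array in turn. Leaving out reverted array 3 ended the calls of the other 5, with an adjusted p of 0.095 for Nifk, 0.0776 for Utp14a and for Aatf, 0.155 for Utp4 and 0.135 for Utp25. Leaving out quiescent array 1 or reverted array 4 also ended all 5 of these calls. Quiescent array 2 ended those of Nifk (0.0802), Aatf (0.0575), Utp4 (0.0894) and Utp25 (0.105), reverted array 2 those of Nifk (0.0771), Utp4 (0.0866) and Utp25 (0.105), and quiescent array 3 and reverted array 1 those of Utp4 (0.0886 and 0.0515) and Utp25 (0.105 and 0.0752).

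Other rises past the limma test with Benjamini-Hochberg adjustment were those of Thbs1, which encodes the matricellular protein thrombospondin 1 (1.00, adjusted p = 0.00947), the adhesion receptor Adgrg6 (1.04, adjusted p = 0.00171), the unconventional myosin Myo1d (1.06, adjusted p = 0.00171), the protease inhibitor gene Serpina3n (1.03, adjusted p = 0.00829), the vitronectin gene Vtn (0.97, adjusted p = 0.0373) and the ephrin receptor Epha3 (0.89, adjusted p = 0.0111). Falls included the microtubule protein gene Map2 (-0.32, adjusted p = 0.0116), the ciliary neurotrophic factor receptor Cntfr (-0.56, adjusted p = 0.0449) and the synapsin gene Syn3 (-0.50, adjusted p = 0.0241). Vtn lost its call without any array except quiescent 2 or 4 or reverted 2, with a highest adjusted p of 0.117, Cntfr without any except quiescent 2, with a highest of 0.113, and Syn3 without any except quiescent 4 or reverted 1 or 2, with a highest of 0.0831. For Steap2, which rose by 0.67, another probe set at a level of 5.72 had a change of -0.01, and this was the one called gene whose probe sets differed in sign. Its adjusted p was 0.0536 without quiescent array 2, 0.0776 without reverted array 3 and 0.0672 without reverted array 4. With the hepatocyte covariate all of these calls ended except those of Adgrg6, Myo1d and Epha3, with a highest adjusted p of 0.132 (Cntfr), and with the immediate early gene covariate all except those of Thbs1, Adgrg6, Myo1d and Serpina3n, with a highest of 0.172 (Vtn).

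Of the 35 splits of the 8 arrays into 4 and 4, only the real one gave as many as 142 changed genes, and the highest other split gave 1. For changes of at least 1.5-fold the real split gave 59 and the highest other 0, and again 1 of 35 splits, the real one, reached that count. This argues against chance for both counts but cannot exclude it, since 1 of 35 is the smallest share possible. The other splits also mix the groups, so a real difference would widen their spread and lower their counts. As many as 12 shifted lists were found in 4 of 35 splits, with a highest other count of 19, so chance cannot be excluded for the number of lists.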
